A study of Solanum lycopersicum with 24 samples.

How the data were processed

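Leaf RNA of tomato was sequenced in 24 libraries. The plants were wild type (WT) or the line βca3, named after the carbonic anhydrase βCA3. They were kept for 2 days at ambient CO2 (400 µmol per mol) or elevated CO2 (800 µmol per mol) and then given a mock treatment or the bacterium Pseudomonas syringae pv. tomato DC3000 (Pst). This makes 8 groups of 3 libraries, taken from the sample titles. Plants were 5 weeks old when moved to the CO2 cabinets, per the labels' protocols. The time from inoculation to sampling and the kind of βca3 lesion are not given in the sources used here. The labels number the replicates without saying that they were separate plants, so p-values measure only the spread between these samples, which may be technical.

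The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2. They name the mouse assembly mm8 as the build, which cannot hold tomato genes, while the chromosome names of the deposited table carry the tomato prefix SL3.0. Coordinates are given as that table lists them. Per the file headers, the deposited table holds an estimated count and an FPKM value (fragments per kilobase of transcript, scaled to the size of the library) for each of 27474 genes and each library. The estimated counts held 0 fractional values, so none was rounded. How reads shared between similar genes were divided, and whether strand was used, are not given in the sources used here. Gene names are the descriptions paired with the gene IDs in the same table, which 25975 genes have. The RefSeq name table supplied for the species matched 0 of the IDs and was not used. The table had 0 unnamed genes and 0 columns of other samples.

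The deposited counts are larger than the number of sequenced fragments. Low values fell on multiples of 3.67 to 3.74, read here as the worth of 1 read pair. Libraries summed to 62.4 M to 81.2 M deposited counts, or 16.9 M to 22 M read pairs on this scale. A gene at 0 was bounded by a floor of 3 read pairs per library, and fold changes against a group at 0 in all its libraries are given as at least that bound. Such floors cover counting error only. Genes were kept where FPKM was at least 1 in at least 3 of the 24 libraries, which left 19877.

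Tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That plan assumed a table of FPKM alone and named limma on log2(FPKM + 1). Because the table also holds estimated counts, the test used is the quasi-likelihood test of edgeR 4.0.16 with TMM scaling and robust estimation, fitted to the 8 group means over all 24 libraries, and limma became an alternative. There were 17 comparisons: 12 between pairs of groups, the genotype difference averaged over 4 conditions, and 4 interactions. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene is called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE), and errors of FPKM are standard deviations (SD, n = 3). The named genes are the 10 largest rises and the 10 largest falls among called genes with an informative description and, in comparisons of 2 groups, no overlap between libraries. For comparisons of 3 libraries with 3, chance alone gives no overlap in 10% of genes. Up to 4 members with the smallest adjusted p are added for each gene list described, along with all carbonic anhydrases. Lower-ranked genes were left out in the comparisons of Pst or CO2 in βca3 and in the interactions, and list members where space was short. Genes named outside this rule are said to be so.

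The 27 gene lists were defined by words in the descriptions. Each was tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. The test was repeated with an estimated correlation and, for the clock, stomata and disease resistance lists, without members of another function. Calls were also counted with p-values adjusted over the list alone. Gene Ontology terms were tested after the data had been examined, by Fisher's exact test over the 14422 annotated genes, with adjustment over 1113 terms.

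Alternatives were median-of-ratios scaling, no filter on low values, a replicate block, a fit of only the 6 libraries compared, pseudocounts of 1 and 0.1 on FPKM with limma, DESeq2 1.42.0, counts divided by the step of 1 read pair, leaving out each library, and leaving out 4 together. Same-numbered replicates were checked for shared deviations from their group means. In 1 comparison of 2 groups, elevated with ambient CO2 in Pst-inoculated WT, all 3 pairs correlated above 0.1 (0.41, 0.11 and 0.33). On the data alone, pairs were used there to judge chance, not in the main fit. No 2 libraries were alike enough to be the same library.

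The steps were tested on counts simulated from the real means and library sizes of 19877 genes, 100 changed 2-fold and 100 4-fold. For Pst in WT at ambient CO2, edgeR recovered 59% and 90% and called 6 unchanged genes. With only the 6 libraries the values were 34%, 78% and 11, and with DESeq2 66%, 94% and 40. For Pst by CO2 in WT edgeR recovered 34% and 80%, and for the 3-way interaction 15% and 61%, calling 4 in each. The real Pst comparison called 14067 genes, far more than changed here, so these false calls do not measure its error. Other versions were R 4.3.3 and Python 3.11.15.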

Results

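The study asked how elevated CO2 and infection with Pst, the bacterial speck pathogen, change gene expression in tomato leaves, and what the carbonic anhydrase βCA3 contributes. Transcript levels were measured in 24 leaf libraries: WT and βca3 plants, at ambient or elevated CO2, after a mock treatment or Pst, with 3 libraries in each of the 8 groups. Each library held 16.9 M to 22 M read pairs by the scale of the deposited counts. The 10 most abundant genes took 6.1% to 13.7% of a library. The first principal component, which carried 69% of the variance, parted Pst-inoculated from mock-inoculated leaves. The median SD of replicates in log2 CPM ran from 0.135 in mock-inoculated WT at ambient CO2 to 0.259 in Pst-inoculated WT at elevated CO2.

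Carbonic anhydrases, which interconvert CO2 and bicarbonate, are given first because the βca3 line is named after one. The gene ID of βCA3 is not given in the sources used here, so none of the 12 annotated genes was taken as the target, and the genotype labels could not be checked through it. The gene described as carbonic anhydrase (Solyc02g067750.3, chromosome 2, 38430301 to 38432844) stood at 0.463 ± 0.0283 FPKM in mock-inoculated WT at ambient CO2 and at 335 ± 81.9 after Pst, a log2 rise of 9.52 (edgeR adjusted p = 3.7e-07). In βca3 it went from 0.175 ± 0.237 to 1830 ± 536, a log2 rise of 13.35 (7.4e-08). At elevated CO2 the same gene went from 0.348 ± 0.426 to 131 ± 57.6 FPKM in WT and from 4.43 ± 4.28 to 609 ± 163 in βca3 (log2 rises of 8.58 and 7.19). It was higher in βca3 than in WT in mock-inoculated leaves at elevated CO2 (log2 3.57, adjusted p = 0.019) and over the mean of the 4 conditions (1.71, 0.0091). Carbonic anhydrase isoform 1 (Solyc02g086820.3, chromosome 2, 50071797 to 50075339) fell under Pst at ambient CO2 from 2090 ± 199 to 311 ± 212 FPKM in WT (log2 -2.72, adjusted p = 0.00032) and from 1680 ± 64.9 to 211 ± 89.7 in βca3 (-2.96, 0.00018). Carbonic anhydrase 2 1 (Solyc05g005490.3) fell from 154 ± 25.3 to 46.2 ± 1.97 FPKM in WT at ambient CO2 and was higher at elevated than at ambient CO2 after Pst, at 91.0 ± 24.8 (log2 0.91, adjusted p = 0.0069). Its response to Pst in WT differed between the CO2 levels (log2 1.15, adjusted p = 0.013).

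Alpha carbonic anhydrase 1 (Solyc09g009830.3) fell under Pst in all 4 comparisons, by 2.11 and 1.71 in WT and by 1.88 and 1.15 in βca3 on the log2 scale, and was higher in βca3 over the mean of the 4 conditions (0.71, edgeR adjusted p = 0.0074). The mitochondrial gamma carbonic anhydrase 2 (Solyc04g080570.3) rose under Pst in all 4, by 0.54, 0.24, 0.36 and 0.58 on the same scale. Beta carbonic anhydrase 5 (Solyc09g010970.3) rose at ambient CO2, by 0.50 in WT and 0.45 in βca3, and did not pass at elevated CO2. Gamma carbonic anhydrase 1 (Solyc02g062600.3) rose in WT at ambient CO2 (0.47) and in βca3 at elevated CO2 (0.40), and alpha carbonic anhydrase 7 (Solyc11g069640.2) in WT at ambient CO2 (0.94). A second gamma carbonic anhydrase 1 (Solyc02g085040.3) passed in no comparison. Gamma carbonic anhydrase-like 2 (Solyc03g019720.4) was higher at elevated CO2 in Pst-inoculated βca3 (0.30) and in βca3 over the 4 conditions (0.15). The nectarin-3-like (Solyc06g075050.2) and alpha carbonic anhydrase 7-like (Solyc10g083890.2) genes stayed under the filter, at no more than 0.571 and 0.964 FPKM in any group mean.

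**Figure D1:**
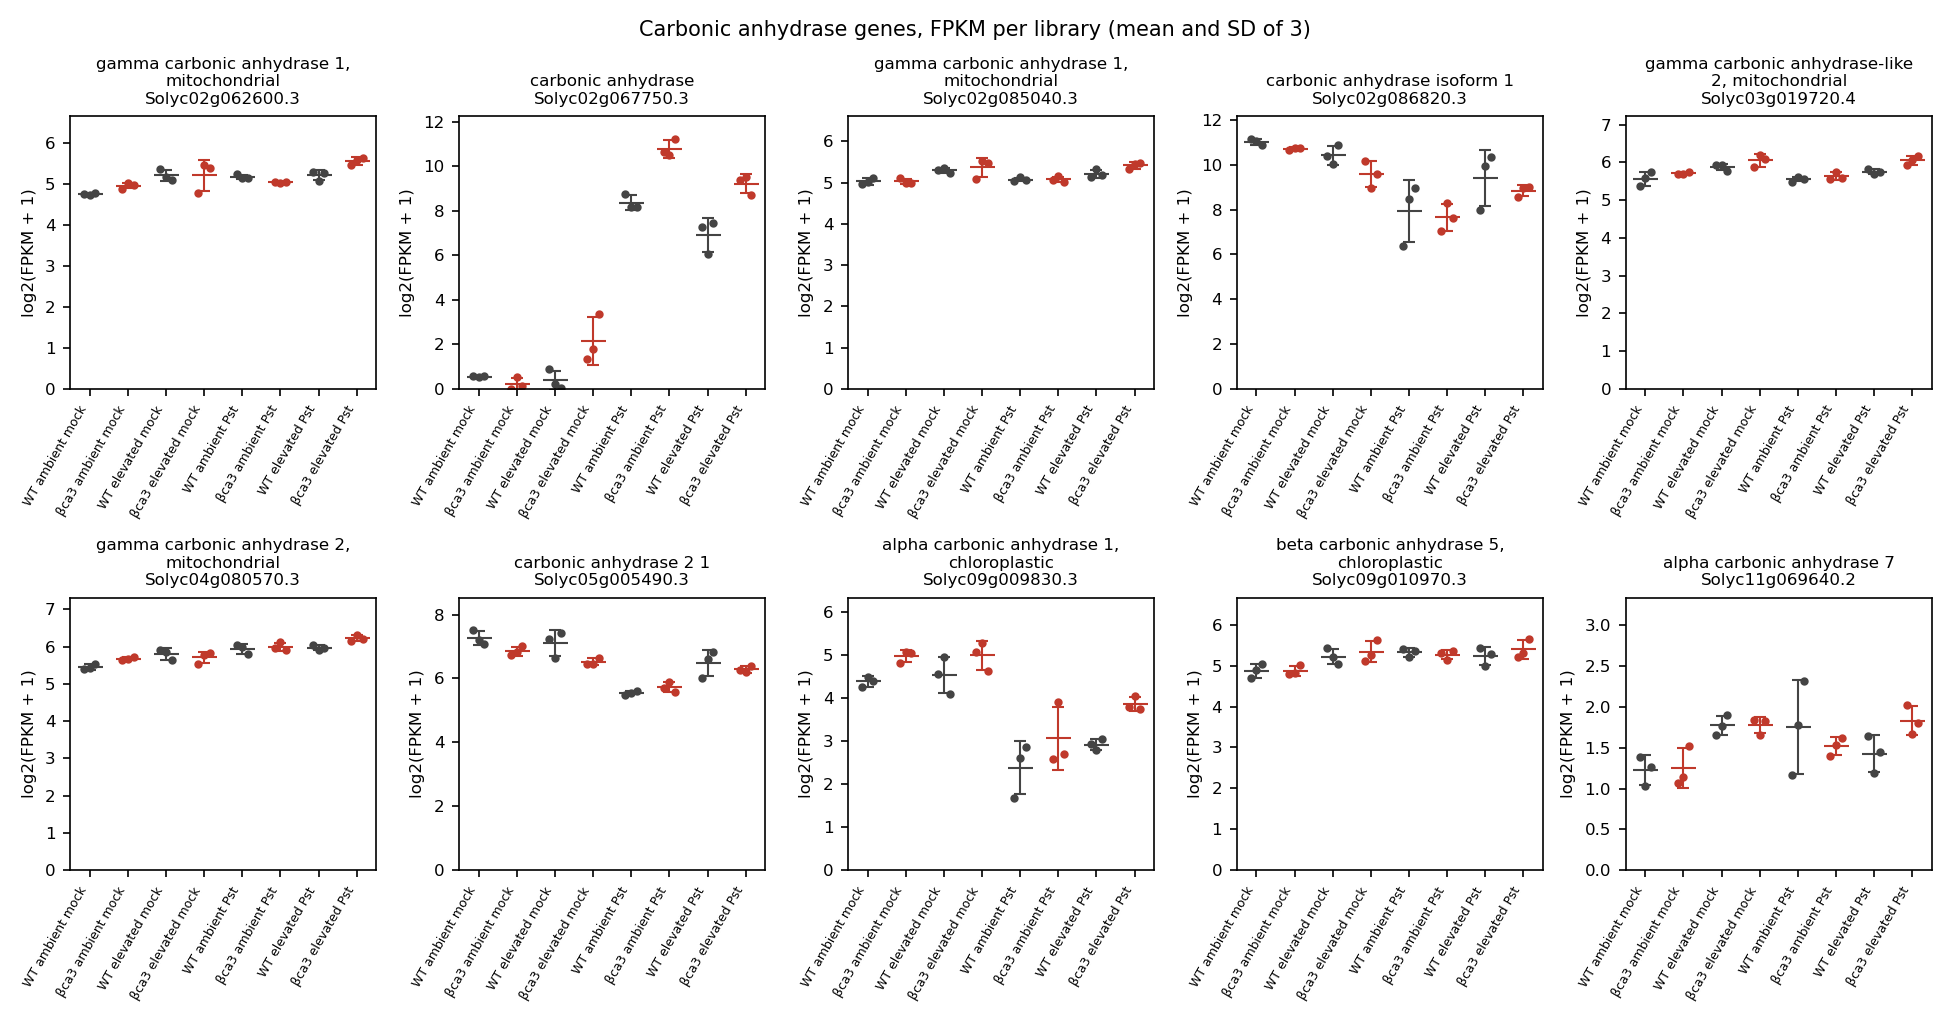
Expression of the 10 tested carbonic anhydrase genes as log2(FPKM + 1) in the 8 groups; points are libraries, bars the mean and SD of 3, with WT in grey and βca3 in red. Solyc02g067750.3 lies above 100 FPKM in the mean of each Pst-inoculated group and at 4.43 FPKM or less in the mean of each mock-inoculated group.

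Pst changed most of the leaf transcriptome of WT at ambient CO2. Polyphenol oxidase F (Solyc08g074630.2, chromosome 8, 58876218 to 58877981), which oxidises phenols in wounded tissue, rose from 15 ± 6.05 to 3740 ± 186 FPKM, a log2 change of 8.01 (SE 0.43, edgeR adjusted p = 2.95e-10). Proteinase inhibitor I-B-like (Solyc09g089520.3) rose from 4.81 ± 1.39 to 2660 ± 161. Jasmonate ZIM-domain protein 1 (Solyc12g009220.2), a repressor of jasmonate signalling, rose from 15.7 ± 2.45 to 846 ± 132 and allene oxide cyclase (Solyc02g085730.3), an enzyme of jasmonate synthesis, from 131 ± 28 to 2080 ± 228. The photosystem II 10 kDa polypeptide (Solyc07g066310.3) fell from 9750 ± 296 to 1950 ± 880 FPKM. In all, 7371 genes were higher and 6696 lower.

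Of 53 wound-defence genes (proteinase inhibitors, polyphenol oxidases and the like), 46 rose and 4 fell, with 47 and 4 adjusted over the list alone, and their median log2 change was 6.04 (camera adjusted p = 7.1e-16, and adjusted p = 0.051 with an estimated correlation). Beside the genes above, polyphenol oxidases E-like (Solyc08g074650.3) and B (Solyc08g074683.1) rose by 9.60 and 7.52. Members of these families are similar in sequence, and the split of reads between them is uncertain. Of 49 jasmonate genes 27 rose and 16 fell, the same adjusted over the list alone, with a median of 1.34 (adjusted p = 0.011, and adjusted p = 0.41 with an estimated correlation). TIFY 10b-like (Solyc12g049400.2) and salt responsive protein 1 (Solyc03g122190.3) rose by 6.14 and 3.81. Of 61 WRKY transcription factors 43 rose and 10 fell, again the same adjusted over the list alone, with a median of 1.32 (adjusted p = 3.9e-05, and adjusted p = 0.47 with an estimated correlation). WRKY 53 (Solyc08g008280.3) rose from 10.3 ± 0.545 to 215 ± 20.3 FPKM, and WRKY 71 (Solyc02g071130.3), WRKY 6 (Solyc02g032950.3) and WRKY 71-like (Solyc07g056280.3) by 6.71, 2.76 and 4.31 on the log2 scale. Of 83 phenylpropanoid genes 44 rose and 20 fell, 46 and 20 adjusted over the list alone, with a median of 0.76 (adjusted p = 0.0034, and adjusted p = 0.41 with an estimated correlation). They included caffeoylshikimate esterase (Solyc03g119980.3, 2.73) and 4-coumarate-CoA ligase (Solyc03g117870.3, 3.46). Of 285 ribosomal protein genes 181 rose and 56 fell, the same adjusted over the list alone, with a median of 0.39 (adjusted p = 0.023, and adjusted p = 0.85 with an estimated correlation).

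Of 80 light-harvesting and photosystem genes 63 fell and 2 rose under Pst in WT at ambient CO2, 63 and 3 adjusted over the list alone, with a median of -2.78 (camera adjusted p = 1.7e-07, and adjusted p = 0.77 with an estimated correlation). Photosystem I subunit IV A (Solyc06g083680.3) fell by 2.44, TAB2 (Solyc02g005200.3) by 1.88 and chlorophyll a-b binding protein 13 (Solyc12g011450.2) by 2.92. Of 35 Calvin cycle genes 29 fell and 4 rose, the same adjusted over the list alone, with a median of -2.17 (adjusted p = 8.4e-05, and adjusted p = 0.77 with an estimated correlation). The members with the smallest p were not typical of it: a cytoplasmic ribulose-phosphate 3-epimerase (Solyc05g007260.3) and the chaperone subunits Solyc06g075010.3 and Solyc06g075000.3 that bind the Rubisco large subunit rose by 1.61, 2.15 and 1.78, while the chaperone subunit Solyc05g010240.3 fell by 1.31. Of 38 genes of the clock list, which took up the chloroplast gene Ycf68 (Solyc01g020285.1) through a species name, 23 fell and 5 rose, 24 and 5 adjusted over the list alone, with a median of -0.62 (adjusted p = 0.011, and adjusted p = 0.57 with an estimated correlation). EARLY FLOWERING 3 (Solyc12g095900.2) fell by 1.84 and CONSTANS-LIKE 6 (Solyc03g083400.3) and 16 (Solyc04g007210.3) fell by 2.92 and 4.17, while APRR1 (Solyc06g069697.1) rose by 1.70.

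The largest rises were of genes at 0 in all mock-inoculated WT libraries at ambient CO2. 2-Alkenal reductase-like (Solyc03g007200.2) reached 9.98 ± 1.87 FPKM, at least 174-fold higher. The others were salicylate carboxymethyltransferase-like (Solyc09g091540.1, at least 123-fold), bHLH14-like (Solyc08g083170.1, at least 76.7-fold), 8-hydroxygeraniol dehydrogenase-like (Solyc11g010980.2, at least 76.6-fold), basic 7S globulin-like (Solyc08g076620.1, at least 61.2-fold) and anthocyanidin 3-O-glucosyltransferase 2-like (Solyc09g098080.3, at least 59.4-fold). A desiccation-related protein (Solyc02g062390.3, at least 52.8-fold), MYB1R1-like (Solyc08g065380.3, at least 46.0-fold), methanol O-anthraniloyltransferase (Solyc08g005760.1, at least 45.3-fold) and a serine protease inhibitor (Solyc03g098770.1, at least 44.2-fold) followed. Among the largest falls, the genes at 0 after Pst were glutathione S-transferase U17-like (Solyc05g006750.3, at least 27.2-fold lower), guanylate-binding protein 2-like (Solyc05g041770.2, 26.4), NRT1/PTR family 4.6 (Solyc03g113250.3, 19.6), beta-glucosidase 11-like (Solyc01g081170.2, 11.3), auxin-induced 15A-like (Solyc01g110600.2, 5.91), EPIDERMAL PATTERNING FACTOR-like 6 (Solyc07g008205.1, 5.66), a sugar transporter N3-like (Solyc03g097580.3, 4.20), BASS1 (Solyc10g038100.1, 3.01) and 12-oxophytodienoate reductase 1-like (Solyc11g032225.1, 2.81), each value being the least fold drop. Chloroplastic fructose-1,6-bisphosphatase-like (Solyc10g086720.2) fell by 8.02 on the log2 scale, from 2.08 FPKM. Adjusted p-values of these 20 genes by edgeR were 0.000786 or smaller.

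At elevated CO2, polyphenol oxidase F (Solyc08g074630.2) rose under Pst in WT from 13.1 ± 3.48 to 1340 ± 306 FPKM, a log2 change of 6.75 (SE 0.41, edgeR adjusted p = 3.94e-09), and proteinase inhibitor I-B-like (Solyc09g089520.3) from 7.25 ± 3.36 to 1210 ± 367. There were 5301 genes higher and 4474 lower. Of the wound-defence genes 42 rose and 2 fell, the same adjusted over the list alone, with a median of 4.22 (camera adjusted p = 1.5e-24, and adjusted p = 0.010 with an estimated correlation), among them polyphenol oxidases E-like (Solyc08g074650.3, 7.43) and B (Solyc08g074683.1, 5.16). Of the jasmonate genes 24 rose and 8 fell, 25 and 8 adjusted over the list alone, with a median of 0.65 (adjusted p = 0.00083, and adjusted p = 0.18 with an estimated correlation). Of the WRKY genes 31 rose and 10 fell, the same adjusted over the list alone, with a median of 0.60 (adjusted p = 0.0018, and adjusted p = 0.70 with an estimated correlation), with WRKY 71 (Solyc02g071130.3) rising by 5.62.

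Of 285 ribosomal protein genes 177 rose and 17 fell in WT at elevated CO2, 181 and 24 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 2.8e-06, and adjusted p = 0.70 with an estimated correlation). In βca3 187 rose and 47 fell at ambient CO2 (188 and 49 adjusted over the list alone, median 0.43, adjusted p = 0.0013, and adjusted p = 0.76 with an estimated correlation) and 179 and 7 at elevated CO2 (182 and 8, 0.38, adjusted p = 2.3e-10, and adjusted p = 0.61 with an estimated correlation). Of the light-harvesting genes 14 fell and 0 rose in WT at elevated CO2, with a median of -0.99 (adjusted p = 2.2e-05, and adjusted p = 0.70 with an estimated correlation), and 0 passed in either direction adjusted over the list alone. Of the Calvin cycle genes 5 fell and 4 rose there, 1 and 4 adjusted over the list alone, with a median of -0.75 (adjusted p = 0.042, and adjusted p = 0.70 with an estimated correlation).

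Among the largest rises in WT at elevated CO2, glucan endo-1,3-beta-glucosidase B (Solyc01g060020.3), which attacks beta-glucans of cell walls, reached 60.1 ± 49.8 FPKM from 0, at least 478-fold higher. Receptor-like protein 12 (Solyc01g005720.3, at least 224-fold), LURP-one-related 11-like (Solyc00g100880.3, at least 119-fold), TSI-1 (Solyc09g090990.2, at least 76.6-fold), TIFY 5A-like (Solyc08g036505.1, at least 47.8-fold) and an acyltransferase of pelargonidin glucosides (Solyc12g005440.1, at least 32.7-fold) followed. The last were bHLH14-like (Solyc08g083170.1, at least 28.3-fold), proteinase inhibitor I-B-like (Solyc09g089490.3, at least 24.8-fold), nudix hydrolase 2-like (Solyc05g016690.3, at least 24.7-fold) and cytochrome P450 71D7-like (Solyc06g066230.3, at least 21.3-fold). The largest falls on the log2 scale were of myb-like protein O (Solyc06g068130.3, -5.93), the blue-light receptor adagio protein 1 (Solyc07g017740.3, -5.58) and ATHB-40-like (Solyc02g062960.3, -5.58). Guanylate-binding protein 2-like (Solyc05g041770.2, -4.53), the sugar transporter N3-like (Solyc03g097580.3, -4.16), NRT1/PTR family 7.3 (Solyc01g080870.3, -4.11) and xyloglucan endotransglucosylase XTH9 (Solyc12g011030.2, -4.08) came next. They were followed by ethylene response factor 3-like (Solyc06g065820.3, -4.01), a mitochondrial ATP synthase beta subunit (Solyc02g091130.3, -3.98) and late embryogenesis abundant protein 76-like (Solyc02g077970.3, -3.95). Adjusted p-values of these 20 genes ran up to 0.0411 in edgeR.

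**Figure D2:**
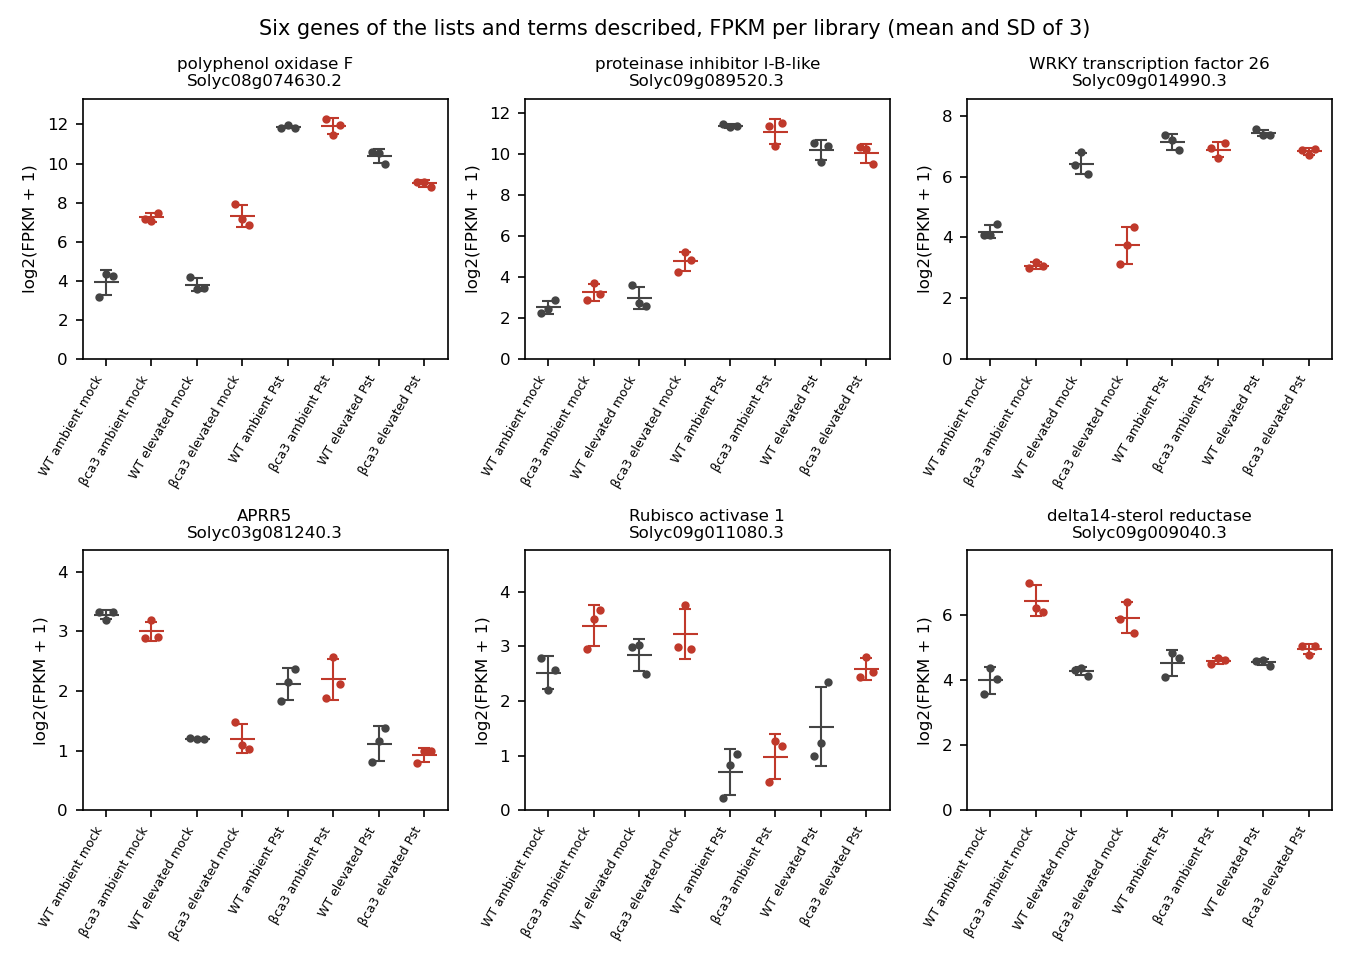
Expression of 6 genes as log2(FPKM + 1) in the 8 groups; points are libraries, bars the mean and SD of 3, with WT in grey and βca3 in red. Polyphenol oxidase F goes from 15 to 3740 FPKM under Pst in WT at ambient CO2, while APRR5 is lower at elevated than at ambient CO2 in each of the 4 pairs of groups.

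In βca3 at ambient CO2, serine protease inhibitor 5-like (Solyc03g098760.2) rose under Pst from 1.21 ± 1.13 to 2660 ± 623 FPKM, a log2 change of 11.13 (SE 0.75, edgeR adjusted p = 4.91e-09). In all 7025 genes were higher and 6649 lower. WT and βca3 called 6238 genes higher together, where independent lists give 2605.1, and 5652 lower, where independent lists give 2239.9. These are separate libraries.

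Of the wound-defence genes 40 rose and 5 fell in βca3 at ambient CO2, the same adjusted over the list alone, with a median of 3.89 (camera adjusted p = 3.8e-11, and adjusted p = 0.28 with an estimated correlation). Polyphenol oxidases E-like (Solyc08g074650.3) and B (Solyc08g074683.1) and proteinase inhibitor I-B-like (Solyc09g089520.3) rose by 12.03, 5.92 and 8.08. Of the WRKY genes 42 rose and 12 fell, 43 and 12 adjusted over the list alone, with a median of 1.13 (adjusted p = 4.4e-06, and adjusted p = 0.46 with an estimated correlation). Of the light-harvesting genes 51 fell and 2 rose, the same adjusted over the list alone, with a median of -2.18 (adjusted p = 4.4e-06, and adjusted p = 0.76 with an estimated correlation). Of the Calvin cycle genes 29 fell and 2 rose, the same adjusted over the list alone, with a median of -2.11 (adjusted p = 4.4e-06, and adjusted p = 0.73 with an estimated correlation).

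The largest rises in βca3 at ambient CO2 were again of genes at 0 in mock-inoculated leaves. The type-2 proteinase inhibitors CEVI57 (Solyc03g020050.3), at 1320 ± 299 FPKM, and Solyc03g020060.3 were at least 7450-fold and 1800-fold higher.

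In βca3 at elevated CO2, serine protease inhibitor 5-like (Solyc03g098760.2) rose under Pst from 2.70 ± 0.521 to 526 ± 231 FPKM, a log2 change of 7.67 (SE 0.65, edgeR adjusted p = 2.93e-07). Proteinase inhibitor I-B-like (Solyc09g089520.3) rose from 27 ± 9.0 to 1080 ± 318. The plastid phosphoenolpyruvate/phosphate translocator 2 (Solyc02g086650.3) fell from 84.6 ± 30.9 to 6.29 ± 3.05. There were 4300 genes higher and 3255 lower, of which 3695 and 2452 were called the same way in WT at elevated CO2, where independent lists give 1146.8 and 732.6.

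Of the wound-defence genes 39 rose and 5 fell in βca3 at elevated CO2, 39 and 6 adjusted over the list alone, with a median of 2.43 (camera adjusted p = 2.5e-15, and adjusted p = 0.066 with an estimated correlation). Of the WRKY genes 34 rose and 10 fell, 36 and 12 adjusted over the list alone, with a median of 0.77 (adjusted p = 9.3e-06, and adjusted p = 0.28 with an estimated correlation), including WRKY 53 (Solyc08g008280.3, 3.39). Of the light-harvesting genes 39 fell and 0 rose, 48 and 0 adjusted over the list alone, with a median of -1.25 (adjusted p = 3.6e-09, and adjusted p = 0.69 with an estimated correlation).

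In mock-inoculated WT, WRKY 26 (Solyc09g014990.3) stood at 87.3 ± 22.2 FPKM at elevated and 17.4 ± 2.72 at ambient CO2, a log2 change of 2.21 (SE 0.24, edgeR adjusted p = 1.92e-05). WRKY 40 (Solyc03g116890.3) stood at 21.1 ± 4.36 against 1.44 ± 0.166 and ethylene response factor 3 (Solyc10g009110.1) at 117 ± 42.7 against 23.6 ± 7.29. The clock components APRR5 (Solyc03g081240.3) and LNK1-like (Solyc04g009050.3) were lower, at 1.29 ± 0.0127 against 8.74 ± 0.513 and at 0.566 ± 0.121 against 9.09 ± 0.361. CONSTANS interacting protein 1 (Solyc06g073180.3) was at 4.59 ± 0.546 against 68.2 ± 4.94. In all 1392 genes were higher and 524 lower.

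Of 61 WRKY genes 25 were higher and 1 lower at elevated CO2 in mock-inoculated WT, 26 and 1 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 8.6e-11, and adjusted p = 0.12 with an estimated correlation). WRKY 1 (Solyc06g068460.3) was higher by 1.63. Of 119 ethylene-related genes 27 were higher and 1 lower, 33 and 3 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.00023, and adjusted p = 0.16 with an estimated correlation). They included an aminocyclopropane carboxylate synthase-like gene of ethylene synthesis (Solyc08g081550.3, 1.86). Of 457 receptor kinases 87 were higher and 5 lower, 98 and 10 adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0015, and adjusted p = 0.47 with an estimated correlation). Of 38 clock genes 11 were lower and 2 higher, 17 and 2 adjusted over the list alone, with a median of -0.24 (adjusted p = 2.0e-10, and adjusted p = 0.049 with an estimated correlation, or 0.053 without Ycf68). A CONSTANS-like protein (Solyc07g006630.3), APRR1 (Solyc03g115770.3) and APRR9 (Solyc10g005030.3) were lower, at log2 changes of -6.05, -1.65 and -3.63.

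Genes at 0 in mock-inoculated WT at ambient CO2 and present at elevated CO2 were a regulator of gene silencing (Solyc11g071760.3, at least 45.6-fold higher), ERF109-like (Solyc10g050970.1, 22.4), a dehydration-responsive element-binding protein (Solyc08g007830.1, 8.38), SWEET11-like (Solyc06g072640.1, 6.51), synaptotagmin-5-like (Solyc12g009700.2, 5.92) and bZIP 11-like (Solyc03g043900.1, 1.99), each value being the least fold. A second dehydration-responsive element-binding protein (Solyc03g124110.2) was at 15.3 ± 5.42 against 0.0991 ± 0.172 FPKM, and ERF025-like (Solyc06g035700.1), ERF018-like (Solyc07g042230.1) and a second regulator of gene silencing (Solyc11g071750.2) were higher by 7.01, 5.89 and 5.88. Besides those above, the largest falls were of REVEILLE 8 (Solyc10g084370.2, -4.17), pathogenesis-related protein PR-5 (Solyc08g080660.1, -3.83), cyclic dof factor 1-like (Solyc03g115940.3, -3.62), myosin-2 heavy chain (Solyc12g038430.2, -3.38) and ACI112 (Solyc01g096630.3, -3.34). The ubiquitin ligase XERICO (Solyc05g010170.1) went to 0 from 0.130 FPKM, both within the floor. Adjusted p-values of these genes in edgeR were 0.042 or smaller. The total of 1916 called genes fell to 1129 and 1047 without ambient mock WT replicate 1 or 2, and to 1085 and 1126 without elevated mock WT replicate 1 or 2. A fit of the 6 libraries with a replicate block called 1085.

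After Pst, WT leaves at elevated CO2 held less transcript of several proteinase inhibitors than leaves at ambient CO2. Cysteine protease inhibitor 8-like (Solyc03g098710.1) stood at 151 ± 21.4 against 1190 ± 627 FPKM, a log2 change of -3.06 (SE 0.59, edgeR adjusted p = 0.00356). Proteinase inhibitor 1-like (Solyc09g089530.3) was at 501 ± 94.3 against 1790 ± 317 and a type-2 proteinase inhibitor (Solyc03g020060.3) at 39.4 ± 26.9 against 468 ± 444. Cytosolic fructose-1,6-bisphosphatase (Solyc04g071340.4) was higher, at 139 ± 100 against 20.7 ± 15.2. There were 2264 genes higher and 1692 lower.

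Of 53 wound-defence genes 18 were lower and 1 higher at elevated CO2 in Pst-inoculated WT, 24 and 2 adjusted over the list alone, with a median of -1.08 (camera adjusted p = 1.2e-08, and adjusted p = 0.47 with an estimated correlation). Polyphenol oxidase E-like (Solyc08g074650.3) and the type-2 inhibitor genes Solyc03g020080.3 and Solyc03g020070.3, listed by ID and of uncertain description, were lower, at -2.06, -3.86 and -2.99. Of 35 Calvin cycle genes 19 were higher and 2 lower, 27 and 2 adjusted over the list alone, with a median of 1.06 (adjusted p = 1.5e-06, and adjusted p = 0.86 with an estimated correlation). Fructose-1,6-bisphosphatases of chloroplast (Solyc10g086720.2) and cytosol (Solyc12g056530.2) were higher by 5.79 and 0.57. Of 80 light-harvesting genes 28 were higher and 11 lower, 36 and 12 adjusted over the list alone, with a median of 1.19 (adjusted p = 0.0016, and adjusted p = 0.86 with an estimated correlation). The members with the smallest p were lower, all 4 being copies of chloroplast-encoded genes: P700 apoprotein A1 (Solyc01g018090.2, -4.31), 2 copies of photosystem II D2 (Solyc00g230080.1, -2.26, and Solyc09g055950.1, -2.76) and CP43 (Solyc11g045260.1, -2.29). Ycf68 (Solyc01g020285.1), also of chloroplast origin by its description, was lower (-3.17).

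Genes at 0 in Pst-inoculated WT at ambient CO2 and higher at elevated CO2 were glutathione S-transferase U17-like (Solyc05g006750.3, at least 5.62-fold), beta-glucosidase 11-like (Solyc01g081170.2, at least 4.27-fold), NRT1/PTR family 4.6 (Solyc03g113250.3, at least 3.66-fold) and 12-oxophytodienoate reductase 1-like (Solyc11g032225.1, at least 1.17-fold). NRT1/PTR family 7.3-like (Solyc07g061910.1) and BASS1 (Solyc10g038100.1) lay within the floor. RADIALIS (Solyc01g109655.1, 6.13), TGA2.3-like (Solyc02g075625.1, 5.40) and protein phosphatase 2C 34 (Solyc01g065700.3, 4.99) were also higher. The largest falls beside those above were of peroxidase 72 (Solyc03g033710.3, -4.99), kiwellin-like (Solyc11g069880.1, -3.53), zinc finger protein 5-like (Solyc05g006310.2, -3.31), acetylornithine deacetylase-like (Solyc08g076980.3, -3.29), a late embryogenesis abundant protein (Solyc03g116390.3, -3.22) and purple acid phosphatase 17 (Solyc03g098010.3, -3.07). Adjusted p-values in edgeR were 0.0477 or smaller. Against these 3956 calls, a fit of the 6 libraries alone gave 12, and 2631 with the replicate block. Leaving out ambient Pst WT replicate 1 or 2 gave 1677 and 2588, and elevated Pst WT replicate 2 or 3 gave 1452 and 1352.

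In mock-inoculated βca3, ethylene response factor 4 (Solyc05g052030.1) was higher at elevated than at ambient CO2, at 179 ± 21.6 against 29.9 ± 2.51 FPKM, a log2 change of 2.42 (SE 0.32, edgeR adjusted p = 0.00014). WRKY 81 (Solyc09g015770.3) was at 106 ± 48.6 against 16.6 ± 2.96, and APRR5 (Solyc03g081240.3) was lower, at 1.32 ± 0.413 against 7.04 ± 0.949. The antimicrobial peptide gene snakin-2 (Solyc01g111075.1) was at 912 ± 624 against 1.64 ± 0.320. In all 2540 genes were higher and 1066 lower, or 1948 and 1340 with median-of-ratios scaling. With the separate libraries of mock-inoculated WT it shared 612 higher genes, where independent lists give 177.9, and 176 lower genes, where they give 28.1. On the first principal component elevated mock βca3 replicate 1 lay at -84.3, near the ambient libraries (-87.1, -91.7 and -93.1), and replicates 2 and 3 at -42.3 and -36. Without replicate 1, 4884 genes were called. The total of 3606 went to 1681 and 2132 without ambient mock βca3 replicate 2 or 3, to 2128 and 1487 without elevated mock βca3 replicate 2 or 3, to 5524 by limma on log2(FPKM + 1), and to 625 in the 6 libraries with a replicate block.

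Of 61 WRKY genes 17 were higher and 0 lower at elevated CO2 in mock-inoculated βca3, 21 and 1 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 7.1e-05, and adjusted p = 0.51 with an estimated correlation). Of 119 ethylene-related genes 24 were higher and 1 lower, 26 and 1 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.0082, and adjusted p = 0.51 with an estimated correlation). Of 35 Calvin cycle genes 4 were lower and 0 higher, the same adjusted over the list alone, with a median of -0.67 (adjusted p = 4.2e-05, and adjusted p = 0.72 with an estimated correlation). All 4 assist Rubisco assembly: accumulation factor 1.1 (Solyc11g006060.1, -0.80) and chaperone subunits (Solyc01g028810.3, Solyc11g069790.2 and Solyc05g010240.3). Of 38 clock genes 8 were lower and 4 higher, 10 and 7 adjusted over the list alone, and the list did not pass (median 0.09, adjusted p = 0.065).

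In Pst-inoculated βca3, chalcone synthase 1 (Solyc09g091510.3), the entry enzyme of flavonoid synthesis, stood at 109 ± 41.4 FPKM at elevated and 2.57 ± 1.31 at ambient CO2, a log2 change of 5.26 (SE 0.87, edgeR adjusted p = 0.00111). Dihydroflavonol 4-reductase (Solyc02g085020.3) was at 86.9 ± 21.7 against 1.74 ± 1.08 and flavonoid 3',5'-methyltransferase (Solyc09g082660.3) at 103 ± 17.8 against 1.60 ± 0.607. SPX domain-containing protein 1 (SPX1, Solyc12g009480.2), a phosphate sensor, was lower, at 8.65 ± 1.94 against 108 ± 54.8, and polyphenol oxidase F (Solyc08g074630.2) was at 505 ± 53.5 against 3930 ± 1050. Leucoanthocyanidin dioxygenase (Solyc08g080040.3) was higher by 5.35. In mock-inoculated βca3 chalcone synthase 1, dihydroflavonol 4-reductase and leucoanthocyanidin dioxygenase were also higher at elevated CO2, by 3.27, 3.03 and 3.33 (edgeR adjusted p = 0.0089, 0.032 and 0.014), and SPX1 lower there (-2.31) and in Pst-inoculated WT (-1.85). Their CO2 by genotype interactions did not pass (2.91, 2.65, 2.87 and -1.43, adjusted p = 0.11, 0.24, 0.15 and 0.24). In all 1785 genes were higher and 1557 lower, or 1664 and 1796 with median-of-ratios scaling.

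Of 53 wound-defence genes 24 were lower and 0 higher at elevated CO2 in Pst-inoculated βca3, 33 and 1 adjusted over the list alone, with a median of -1.31 (camera adjusted p = 1.4e-13, and adjusted p = 0.097 with an estimated correlation). Polyphenol oxidase E (Solyc08g074620.3), proteinase inhibitor 1-like (Solyc09g089530.3) and cysteine protease inhibitor 8-like (Solyc03g098710.1) fell by 3.20, 2.53 and 3.75. Of 35 Calvin cycle genes 6 were higher and 1 lower, 21 and 1 adjusted over the list alone, with a median of 0.98 (adjusted p = 9.6e-05, and adjusted p = 0.68 with an estimated correlation). Of 140 disease resistance genes 24 were higher and 4 lower, the same adjusted over the list alone, with a median of 0.26 (adjusted p = 0.0032, and adjusted p = 0.68 with an estimated correlation). Without 12 that are no NLR receptors by description, 24 of 128 were higher and 2 lower (adjusted p = 0.00051, and adjusted p = 0.68 with an estimated correlation). Of 17 phloem markers 8 were higher and 0 lower, 9 and 1 adjusted over the list alone, with a median of 0.63 (adjusted p = 0.0032, and adjusted p = 0.23 with an estimated correlation), among them PHLOEM PROTEIN 2-like A9 (Solyc02g031740.3, 1.10). Of 38 clock genes 8 were lower and 3 higher, 11 and 4 adjusted over the list alone, with a median of -0.21 (adjusted p = 0.014, and adjusted p = 0.68 with an estimated correlation), including APRR5 (Solyc03g081240.3, -2.14).

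Between the separate libraries of Pst-inoculated WT and βca3, 887 genes were higher and 766 lower at elevated CO2 in both, where independent lists give 203.3 and 132.5. The 3342 calls in Pst-inoculated βca3 went to 1521 and 1068 without ambient Pst βca3 replicate 1 or 3, to 1913 and 1289 without elevated Pst βca3 replicate 2 or 3, and to 1476 in the 6 libraries with a replicate block.

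In mock-inoculated leaves at ambient CO2, the sugar-binding protein lectin (Solyc03g116200.2) was higher in βca3 than in WT, at 1510 ± 182 against 12.5 ± 1.25 FPKM, a log2 difference of 6.90 (SE 0.91, edgeR adjusted p = 0.000118). The type-2 proteinase inhibitor TR8 (Solyc11g021060.2) was at 4580 ± 197 against 391 ± 113, threonine dehydratase (Solyc09g008670.3) at 1010 ± 164 against 27.0 ± 20.9, and polyphenol oxidase F (Solyc08g074630.2) at 151 ± 24.2 against 15 ± 6.05. Phenylalanine ammonia-lyase (Solyc10g086180.2), the entry enzyme of phenylpropanoid synthesis, was at 145 ± 50.7 against 43.3 ± 4.98. There were 1119 genes higher and 726 lower in βca3.

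Of 53 wound-defence genes 18 were higher and 5 lower in mock-inoculated βca3 at ambient CO2, 23 and 8 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 3.9e-07, and adjusted p = 0.34 with an estimated correlation). Of 83 phenylpropanoid genes 17 were higher and 1 lower, 18 and 1 adjusted over the list alone, with a median of 0.37 (adjusted p = 0.0005, and adjusted p = 0.34 with an estimated correlation), including caffeoylshikimate esterase (Solyc03g119980.3, 1.12) and 4-coumarate-CoA ligases (Solyc03g117870.3, 1.54, and Solyc06g068650.3, 1.10). Of 19 salicylic acid genes 4 were higher and 0 lower, the same adjusted over the list alone, with a median of 0.11 (adjusted p = 0.023, and adjusted p = 0.58 with an estimated correlation). They were salicylate carboxymethyltransferase-like genes (Solyc04g055260.3, 4.80, and Solyc00g032947.1, at least 3.08-fold from 0) and salicylic acid-binding proteins 2 (Solyc03g044820.3, 1.11, and Solyc03g070380.3, 3.52), which methylate salicylate and remove the methyl group. The light-harvesting list lay lower (median -0.56, adjusted p = 9.4e-05, and adjusted p = 0.87 with an estimated correlation) with 0 of 80 genes passing, also 0 adjusted over the list alone.

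Several genes were present in one genotype and at 0 in the other at ambient CO2 in mock-inoculated leaves. Resistance protein RGA3 (Solyc02g073574.1), bifunctional pinoresinol-lariciresinol reductase (Solyc06g066160.3), a zinc finger BED protein (Solyc04g057787.1), protein phosphatase 7 long form (Solyc01g034010.1), a G-type lectin receptor (Solyc01g014530.2), UPF0183 protein (Solyc02g073571.1) and synaptotagmin-5-like (Solyc12g009700.2) were at least 27.7, 25.9, 12.9, 10.9, 8.28, 7.51 and 2.53 fold higher in βca3, and F-box SKIP23-like (Solyc11g005160.1) was higher by 8.35 on the log2 scale. Another zinc finger BED protein (Solyc12g035225.1), the RB resistance protein (Solyc02g014250.2), CEVI57 (Solyc03g020050.3) and ATPase 8-like (Solyc00g257110.3) were at least 93.3, 43.9, 12.3 and 3.50 fold lower. RB stood at 14.6 ± 1.63 FPKM in WT, and CCCH domain protein 55 (Solyc04g064763.1) at 0.301 ± 0.178 in βca3 against 16.5 ± 0.270. A second CCCH protein 55 (Solyc04g064765.1) and the proteasome beta 1-like pair (Solyc03g033740.3 and Solyc03g033745.1) were lower too, and the split of reads within these pairs is uncertain. Guanylate-binding protein 2-like (Solyc05g041770.2) and ubiquitin-like-specific protease 1B (Solyc08g016581.1) were lower, at -5.75 and -3.43. Leaving out any of the 6 libraries lowered the 1845 calls, to 576, 874 and 865 without WT replicates 1, 2 and 3 and to 864, 782 and 953 without those of βca3. A fit of these 6 libraries alone called 5101, with the replicate block 3344, and DESeq2 called 2926.

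At elevated CO2, mock-inoculated βca3 again held more polyphenol oxidase F (Solyc08g074630.2), at 165 ± 65.7 against 13.1 ± 3.48 FPKM, a log2 difference of 3.62 (SE 0.35, edgeR adjusted p = 4.47e-06). WRKY 26 (Solyc09g014990.3) was lower, at 13.1 ± 5.73 against 87.3 ± 22.2, and so were WRKY 1 (Solyc06g068460.3, -1.67) and 2 genes of WRKY 53 (Solyc08g008280.3, -2.66, and Solyc08g082110.3, -2.67). There were 587 genes higher and 382 lower, or 405 and 412 with median-of-ratios scaling. With the separate libraries at ambient CO2 it shared 209 higher genes, where independent lists give 33, and 80 lower genes, where they give 14. Of 53 wound-defence genes 15 were higher and 0 lower, 24 and 3 adjusted over the list alone, with a median of 1.13 (camera adjusted p = 1.6e-08, and adjusted p = 0.45 with an estimated correlation), including PSI-1.2-like (Solyc07g054720.2, 4.29) and wound-induced proteinase inhibitor 1 (Solyc09g083445.1, 1.90). Of 61 WRKY genes 12 were lower and 4 higher, 13 and 8 adjusted over the list alone (median 0.03, adjusted p = 0.00057 downward, and adjusted p = 0.72 with an estimated correlation). The median and the direction of the test differ in sign here. Of 19 salicylic acid genes 2 were higher and 0 lower, 3 and 0 adjusted over the list alone, with a median of 0.31 (adjusted p = 0.039, and adjusted p = 0.72 with an estimated correlation): Solyc04g055260.3 (3.48) and Solyc03g044820.3 (1.09).

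In mock-inoculated leaves at elevated CO2 the G-type lectin receptor (Solyc01g014530.2) was at 0 in WT and at least 5.15-fold higher in βca3. The BED protein Solyc04g057787.1, a CYP736A12-like copy (Solyc04g054257.1), cannabidiolic acid synthase-like (Solyc02g070110.1), endoglucanase 12 (Solyc11g008820.2), lipid-transfer protein 2-like (Solyc10g075150.2), SKIP23-like (Solyc11g005160.1), an aldo-keto reductase (Solyc09g097960.3) and RGA3 (Solyc02g073574.1) were higher by 5.46, 5.33, 5.12, 5.04, 4.86, 4.85, 4.13 and 4.07. The BED protein Solyc12g035225.1, flavonoid 3'-monooxygenase-like (Solyc08g083500.2), proteasome beta 1-like (Solyc03g033740.3), ATPase 8-like (Solyc00g257110.3), its neighbour Solyc03g033745.1 among the proteasome genes and FLOWERING LOCUS T-like (Solyc11g008640.1) were at 0 in βca3, at least 85.6, 18.9, 9.93, 6.15, 1.26 and 1.20 fold lower. RB (Solyc02g014250.2), ERF025-like (Solyc06g035700.1), an F-box protein (Solyc09g091620.2) and the dehydration-responsive protein Solyc03g124110.2 were at -7.88, -7.20, -7.01 and -6.02. The 969 calls fell to 587 and 541 without WT replicate 1 or 3 and to 406 without βca3 replicate 2. The 6 libraries alone gave 256, with the replicate block 4, and DESeq2 1498.

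After Pst at ambient CO2 the genotypes differed least, with 31 genes higher and 24 lower in βca3. The RB resistance protein (Solyc02g014250.2) stood at 0.0819 ± 0.0807 FPKM in βca3 against 14.0 ± 0.725 in WT, a log2 difference of -7.28. CLASSY4-like (Solyc08g074705.1) was at 0.876 ± 0.485 against 16 ± 3.30 (-4.18), its neighbour CLASSY3-like (Solyc08g074710.1) was lower (-3.46), and neurofilament medium polypeptide (Solyc02g067610.1) was at 18.6 ± 5.79 against 1.10 ± 0.508 (4.06, SE 0.58, edgeR adjusted p = 0.00176). The BED protein Solyc04g057787.1, the G-type lectin receptor (Solyc01g014530.2) and UPF0183 protein (Solyc02g073571.1) were at 0 in WT, at least 6.69, 6.03 and 4.68 fold higher in βca3. RGA3 (Solyc02g073574.1), SKIP23-like (Solyc11g005160.1), 3-hydroxyisobutyryl-CoA hydrolase 1-like (Solyc01g108800.3), DETOXIFICATION 56-like (Solyc08g079730.1) and the F-box proteins Solyc08g013770.3 and Solyc11g006740.2 were higher by 7.99, 7.42, 3.50, 2.82, 2.78 and 2.58. The BED protein Solyc12g035225.1, CCCH protein 55 (Solyc04g064765.1) and the proteasome pair (Solyc03g033740.3 and Solyc03g033745.1) were at 0 in βca3, at least 64.3, 19.2, 12.8 and 1.69 fold lower. CCCH protein 55 (Solyc04g064763.1), ATPase 8-like (Solyc00g257110.3) and an alpha/beta-hydrolase (Solyc09g009540.3) were at -6.05, -4.54 and -1.61. None of the gene lists passed. DESeq2 called 217 genes, an edgeR fit of the 6 libraries alone 10, and that fit with the replicate block 0, with 761 at an unadjusted p under 0.05. Leaving out 4 libraries together, a choice that itself raises counts, gave 172 higher and 846 lower.

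After Pst at elevated CO2, βca3 held more leucoanthocyanidin dioxygenase (Solyc08g080040.3) of anthocyanin synthesis, at 79.1 ± 30.6 against 4.23 ± 4.04 FPKM, a log2 difference of 4.18 (SE 0.91, edgeR adjusted p = 0.0203). Salicylic acid-binding protein 2 (Solyc03g044820.3) was at 32.7 ± 1.27 against 15.5 ± 4.04. Polyphenol oxidase F (Solyc08g074630.2) was lower, at 505 ± 53.5 against 1340 ± 306, and WRKY 17 (Solyc12g096350.2) at 4.80 ± 0.372 against 13.4 ± 1.91. There were 245 genes higher and 268 lower. With the separate libraries at ambient CO2 it shared 19 higher and 22 lower genes, where independent lists give 0.4 and 0.3. Of 19 salicylic acid genes 3 were higher and 0 lower, 5 and 0 adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.00098, and adjusted p = 0.58 with an estimated correlation), including a salicylate methyltransferase (Solyc02g084950.3, 1.67). Of 74 starch and sucrose genes 5 were higher and 0 lower, the same adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0043, and adjusted p = 0.58 with an estimated correlation). They included the sucrose-cleaving invertases Solyc01g100810.3 (0.99) and Solyc03g083910.4 (0.84) and the invertase inhibitors Solyc12g099200.2 (1.14) and Solyc12g099190.1 (1.18). Among 53 wound-defence genes 3 were lower and 0 higher, the same adjusted over the list alone, with a median of -0.37 (adjusted p = 0.0016, and adjusted p = 0.59 with an estimated correlation): polyphenol oxidases F and E (Solyc08g074620.3, -2.79) and arginase 1 (Solyc01g091160.4, -0.59). Of 61 WRKY genes 5 were lower and 1 higher, 11 and 1 adjusted over the list alone, with a median of -0.16 (adjusted p = 0.0033, and adjusted p = 0.64 with an estimated correlation), among them WRKY 53 (Solyc08g082110.3, -1.97, and Solyc08g008280.3, -1.35). The light-harvesting list lay lower too (median -0.69, adjusted p = 2.8e-06, and adjusted p = 0.68 with an estimated correlation), with 0 of 80 genes passing, also 0 adjusted over the list alone.

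In Pst-inoculated leaves at elevated CO2, SKIP23-like (Solyc11g005160.1), protein phosphatase 7 long form (Solyc01g034010.1), the BED protein Solyc04g057787.1, UPF0183 protein (Solyc02g073571.1) and the G-type lectin receptor (Solyc01g014530.2) were at 0 in WT, at least 34.3, 21.1, 6.53, 5.83 and 3.35 fold higher in βca3. RGA3 (Solyc02g073574.1), a receptor-like cytosolic kinase (Solyc01g098440.2), myosin-2 heavy chain (Solyc12g038430.2) and HVA22-like c (Solyc05g007300.3) were higher by 6.53, 5.83, 4.87 and 4.82. CCCH protein 55 (Solyc04g064765.1), the proteasome pair (Solyc03g033740.3 and Solyc03g033745.1) and ERF025-like (Solyc06g035700.1) were at 0 in βca3, at least 16.6, 12.6, 1.73 and 2.65 fold lower. The BED protein Solyc12g035225.1, RB (Solyc02g014250.2), CCCH protein 55 (Solyc04g064763.1), ATPase 8-like (Solyc00g257110.3), the secreted glycoprotein EP1-like (Solyc07g062480.1) and calcium-binding CML19 (Solyc11g071740.2) were at -8.69, -7.81, -6.87, -4.62, -3.80 and -3.26. The 513 calls fell to 172 and 328 without WT replicate 2 or 3 and to 286, 138 and 201 without βca3 replicate 1, 2 or 3. An edgeR fit of the 6 libraries alone gave 67, that fit with the replicate block 0 (3295 at an unadjusted p under 0.05), and DESeq2 1139.

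Over the mean of the 4 conditions 2354 genes were higher and 1380 lower in βca3. Polyphenol oxidase F (Solyc08g074630.2), wound-induced proteinase inhibitor 1 (Solyc09g083445.1), threonine dehydratase (Solyc09g008670.3) and TR8 (Solyc11g021060.2) were higher by 1.39, 1.54, 2.27 and 1.31, with 19 of 53 wound-defence genes higher and 5 lower, 19 and 8 adjusted over the list alone (median 0.38, camera adjusted p = 0.009, and adjusted p = 0.73 with an estimated correlation). Of 19 salicylic acid genes 6 were higher and 0 lower, 9 and 0 adjusted over the list alone (median 0.32, adjusted p = 0.00091, and adjusted p = 0.65 with an estimated correlation), with Solyc04g055260.3 (2.56) and Solyc03g044820.3 (0.88). Of 83 phenylpropanoid genes 25 were higher and 5 lower, 31 and 6 adjusted over the list alone (median 0.23, adjusted p = 0.0093, and adjusted p = 0.73 with an estimated correlation). Of 61 WRKY genes 13 were lower and 4 higher, 14 and 4 adjusted over the list alone (median -0.14, adjusted p = 0.00044, and adjusted p = 0.73 with an estimated correlation), with WRKY 26 (Solyc09g014990.3, -1.23) and 53 (Solyc08g082110.3, -1.56). Of 80 light-harvesting genes 4 were lower and 0 higher, and 0 passed adjusted over the list alone (median -0.43, adjusted p = 2.2e-06, and adjusted p = 0.73 with an estimated correlation), the lowest being a chlorophyll a-b binding protein 3C (Solyc08g067330.1, -1.03).

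The largest mean rises in βca3 were of ATP-dependent helicase rhp16-like (Solyc07g052020.2, 9.88), protein phosphatase 7 long form (Solyc01g034010.1, 9.10), the G-type lectin receptor (Solyc01g014530.2, 8.84), BED proteins (Solyc04g057787.1, 8.48, and Solyc04g057783.1, 7.00), purin-rich alpha 1 (Solyc01g049685.1, 8.30), SKIP23-like (Solyc11g005160.1, 8.02), UPF0183 protein (Solyc02g073571.1, 7.58), RGA3 (Solyc02g073574.1, 7.45) and LAZ1 (Solyc07g051990.2, 6.62). The largest falls were of the BED protein Solyc12g035225.1 (-11.79), the proteasome pair (Solyc03g033740.3, -9.16, and Solyc03g033745.1, -7.10), RB (Solyc02g014250.2, -8.73), CCCH protein 55 (Solyc04g064765.1, -8.40, and Solyc04g064763.1, -6.13), ATPase 8-like (Solyc00g257110.3, -6.61, and Solyc07g005040.3, -5.07), 6-phosphogluconate dehydrogenase (Solyc12g056120.1, -6.23) and oligopeptide transporter 6 (Solyc03g082700.3, -5.21). Most of these fitted values rest on groups at 0 and are no bounds on the fold, and edgeR adjusted p-values ran up to 0.0458.

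In WT the response to Pst depended on the CO2 level for many genes. The rise of proteinase inhibitor 1-like (Solyc09g089530.3), polyphenol oxidase B (Solyc08g074683.1), leucine aminopeptidase 1 (Solyc12g010025.1) and threonine dehydratase (Solyc09g008670.3) was smaller at elevated CO2, by log2 interactions of -3.09, -2.37, -2.39 and -3.15 (edgeR adjusted p = 0.00206, 0.00438, 0.0075 and 0.0139). In all, 1923 interactions were positive and 2012 negative, or 2080 and 1719 with median-of-ratios scaling. Of 53 wound-defence genes 13 were negative and 0 positive, 17 and 1 over the list alone. Their median was -1.38 (camera adjusted p = 5.9e-06, and 0.75 with an estimated correlation). Of 61 WRKY genes 19 were negative and 3 positive, 20 and 4 over the list alone. Their median was -0.59 (adjusted p = 2.6e-05, and 0.75 with an estimated correlation), led by WRKY 40 (Solyc03g116890.3, -3.29). The list was already higher in mock leaves at elevated CO2. Light-harvesting genes fell less (14 of 80 positive and 0 negative, 36 and 3 over the list alone). Their median was 1.74 (adjusted p = 1e-06, and 0.83 with an estimated correlation), with photosystem II gene Solyc07g066310.3 at 1.67. Of 35 Calvin cycle genes 15 were positive and 4 negative, 26 and 4 over the list alone. Their median was 1.41 (adjusted p = 1e-06, and 0.83 with an estimated correlation), led by fructose-1,6-bisphosphatases (Solyc10g086720.2, 6.56, and Solyc12g056530.2, 0.94). The 3935 calls went to 1976 and 2591 without ambient mock WT replicate 1 or 2, 2127 and 1555 without elevated mock 1 or 2, 2264 without ambient Pst 1, and 6099, 1875 and 1549 without elevated Pst 1, 2 or 3.

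The response to Pst differed between the genotypes for fewer genes, 65 with a positive and 228 with a negative interaction over both CO2 levels, and DESeq2 called 563. Polyphenol oxidase F (Solyc08g074630.2), higher in mock βca3 (3.48), rose less there (interaction -4.17, SE 0.33, edgeR adjusted p = 2.57e-06). So did wound-induced proteinase inhibitor 1-like (Solyc09g084490.3, 2.46 and -2.50). TR8 (Solyc11g021060.2, -2.42) rose under Pst in WT at ambient CO2 (1.62) and fell in βca3 (-1.87), and proteinase inhibitor I (Solyc09g084450.3, -3.46) rose in WT (4.17) and did not pass in βca3 (0.02). Among 53 wound-defence genes 19 were negative and 0 positive, 25 and 0 adjusted over the list alone, with a median of -0.90 (camera adjusted p = 5.1e-26, and adjusted p = 0.005 with an estimated correlation). Of 83 phenylpropanoid genes 6 were negative and 0 positive, 11 and 2 adjusted over the list alone, with a median of -0.21 (adjusted p = 0.0036, and adjusted p = 0.38 with an estimated correlation): caffeoylshikimate esterase (Solyc03g119980.3, -0.97), phenylalanine ammonia-lyase (Solyc10g086180.2, -1.43) and 4-coumarate-CoA ligases (Solyc06g068650.3, -1.0, and Solyc03g117870.3, -1.27). Xyloglucan endo-transglycosylase (Solyc12g017240.2, 3.27) and ethylene response factor 5 (Solyc05g052040.1, 2.02) had positive interactions, and ribonuclease 3-like (Solyc07g006570.3, -3.69) and Myb4-like (Solyc06g083900.3, -3.40) negative ones.

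The effect of CO2 differed between the genotypes for 52 genes, 23 positive and 29 negative in βca3, and the 3-way interaction passed for 22, 8 positive and 14 negative. Pectinesterase 3 (Solyc03g123620.4), a cell wall enzyme, and metalloendoproteinase 1 (Solyc04g005040.1) had CO2 interactions of -1.60 and -1.67, and the bHLH factor MYC1 (Solyc08g005050.3) and dnaJ 20 (Solyc05g053760.3) 3-way interactions of 1.62 and -1.57 (edgeR adjusted p = 0.000126 and 0.00212). DESeq2 called 398 and 238. The 52 went to 14 and 25 without ambient mock WT replicate 1 or 3, 21 without elevated mock WT 2, 29 and 30 without ambient Pst WT 2 or 3, and 25 without elevated Pst WT 2. In βca3 they went to 34, 15 and 34 without ambient mock 1, 2 or 3, 118 and 15 without elevated mock 1 or 2, 101 and 23 without ambient Pst 2 or 3, and 17, 19 and 25 without elevated Pst 1, 2 or 3. The 22 went to 11, 13 and 10 without ambient mock WT 1, 2 or 3, 9, 11 and 49 without elevated mock WT 1, 2 or 3, 153, 6 and 12 without ambient Pst WT 1, 2 or 3, and 10 and 8 without elevated Pst WT 2 or 3. In βca3 they went to 9 and 14 without ambient mock 2 or 3, 9 without ambient Pst 1, and 12, 11 and 7 without elevated Pst 1, 2 or 3.

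**Figure D3:**
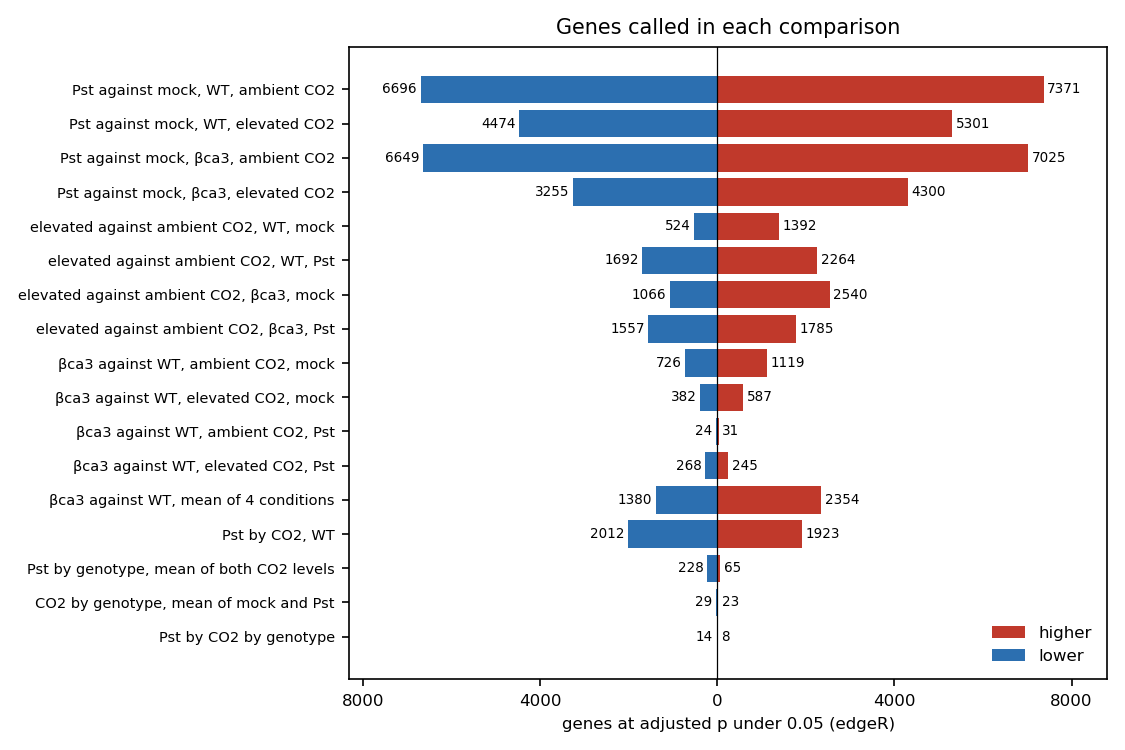
Number of genes at an adjusted p under 0.05 in each of the 17 comparisons, higher or positive in red and lower or negative in blue. Responses to Pst run from 7555 to 14067 genes and the 3-way interaction has 22.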

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

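The tests of a few genes taking most of the counts and of the level in mock-inoculated βca3 were chosen only after the result was seen. The results here drew attention because an interaction test found an effect to differ between groups, and groups of 3 libraries were not tested for outlying samples.

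The response of WT to Pst differed between CO2 levels for 3935 genes, with list medians of -1.38 (wound defence), -0.59 (WRKY), 1.74 (light harvesting) and 1.41 (Calvin cycle). The furthest genes were glutathione S-transferase U17-like (Solyc05g006750.3, 9.87), NRT1/PTR family 4.6 (Solyc03g113250.3, 9.50), a regulator of gene silencing (Solyc11g071760.3, -11.25) and pinoresinol-lariciresinol reductase (Solyc06g066160.3, -10.24). The response to Pst differed between genotypes for 293 genes, with list medians of -0.90 (wound defence) and -0.21 (phenylpropanoid). Flavonoid 3'-monooxygenase-like (Solyc08g083500.2, 5.09), beta-glucosidase 11-like (Solyc01g081170.2, 4.13), salicylate carboxymethyltransferase-like (Solyc00g032947.1, -5.35) and a benzylalcohol acetyltransferase-like gene (Solyc07g052060.2, -4.74) lay furthest. The effect of CO2 differed between genotypes for 52 genes, with dnaJ 8 (Solyc06g068500.3, 1.71), ATHB-12-like (Solyc06g053220.3, 1.39), the monooxygenase Solyc08g083500.2 (-6.17) and PUB22-like (Solyc01g007000.3, -3.55). The 3-way interaction passed for 22, with LYK2 (Solyc02g094010.2, 4.54), GATA factor 8 (Solyc04g015360.3, 2.96), LNK1-like (Solyc04g009050.3, -2.20) and cyclic dof factor 3-like (Solyc02g088070.3, -2.18). The values of the first 7 genes named here, and of Solyc08g083500.2 again for CO2 by genotype, rest on a group at 0 and are no bounds.

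Other splits of the same libraries were counted for each comparison, 100 drawn where there were more. Draws were raised to 100 after a smaller draw, in which CO2 by genotype had still passed, was seen. Chance can be excluded for the genotype difference over 4 conditions (3734, highest other 256, 1 of 100 as large). It cannot where other splits called more, as for Pst by CO2 (3935, highest other 4921, 2 of 100). Nor can it for Pst by genotype (293, 2639, 2), CO2 by genotype (52, 2248, 6) or the 3-way interaction (22, 2433, 7). Splits calling several times the real count point to a structure of the samples. In comparisons of 3 libraries with 3, the 10 splits are too few. The real count and the highest other were 14067 and 1, 9775 and 3, 13674 and 0, and 7555 and 0 for Pst in WT and then βca3 at ambient and elevated CO2. For CO2 in mock and Pst-inoculated WT they were 1916 and 2, and 3956 and 2817, and in βca3 3606 and 4, and 3342 and 0. Between genotypes they were 1845 and 1, and 969 and 390, in mock-inoculated leaves at ambient and elevated CO2, and 55 and 1385, and 513 and 0, after Pst. The 1385 point to such a structure. For CO2 in Pst-inoculated WT, with the numbers read as pairs, the 3 other splits parting as many pairs called at most 0 genes. The 2817 came from a split parting fewer. The pairing is uncertain, so this does not set the 2817 aside. For Pst by CO2 the 35 other splits parting as many pairs of Pst-inoculated WT called at most 2257, and the 4921 came from a split parting fewer.

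The smaller rise under Pst of the wound-defence list in βca3 (median interaction -0.90) was weighed against technical causes. With median-of-ratios scaling the median was -0.89. TMM resists a few dominant genes too, so that cause was not tested. Leaving out any single library gave -0.72 at most, which argues against a single library. The list was higher in mock-inoculated βca3 (median 0.83) and differed by -0.24 after Pst. By these medians the smaller rise lay mostly in the starting level. A biological difference between the lines was not tested apart from this.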

How the results depend on the processing

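DESeq2, divided counts, the block in 6 libraries, the removal of 4 libraries and of list members of another function were chosen only after the data had been examined. Limma on log2(FPKM + 1), planned as the main test, became an alternative then. Over the named genes and all settings, the removal of 4 libraries included, 5130 values kept their call, 445 lost it, 5 gained it and 0 reversed, apart from leaving out 1 library, where 4830 kept it and 882 lost it. Some genes and lists were dropped from the text after these fits had been seen, most of those that had reversed among them, so this covers only what is named here. Of 63 list results 58 lost their call with an estimated correlation and 63 kept it with median-of-ratios scaling and with the block. The cause of the changes below was not tested.

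DESeq2 gave 2926 genes between genotypes in mock leaves at ambient and 1498 at elevated CO2, 217 and 1139 after Pst, and 563, 398 and 238 for Pst by genotype, CO2 by genotype and the 3-way interaction, for which limma with a pseudocount of 0.1 gave 14. With a pseudocount of 1 limma gave 5524 for CO2 in mock βca3. Fits of the 6 libraries compared gave 12 for CO2 in Pst-inoculated WT, and 5101, 256, 10 and 67 between genotypes in the same order. Same-numbered replicates correlated above 0.1 in 24 of 84 pairs (median 0.04), and with a replicate block in the 6 libraries the CO2 counts were 1085 and 2631 in mock and Pst-inoculated WT and 625 and 1476 in βca3, and the genotype counts 3344, 4, 0 and 0. The block over all libraries gave 2455 higher and 1784 lower in Pst-inoculated WT and moved no count by over 1.5 times.

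Leaving out WT ambient Pst 1, WT elevated Pst 1, βca3 elevated mock 1 and βca3 ambient Pst 2 together, chosen because leaving out each alone gave more calls in some comparisons (fewer in others), gave 3862 for CO2 in mock WT, 7294 and 7052 in βca3, and 3707, 3542, 1018 and 2740 between genotypes with 7617 over their mean. The interactions became 6228, 479, 584 and 627. That choice itself raises counts.

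Leaving out 1 library at a time gave 12953 to 13823, 6839 to 9935, 12521 to 13481 and 5182 to 6856 genes for Pst in WT and then βca3 at ambient and elevated CO2. The CO2 counts ran from 1047 to 2179 and 1352 to 5505 in mock and Pst-inoculated WT, and from 1487 to 4884 and 1068 to 4602 in βca3. Between genotypes they ran from 576 to 953, 406 to 1383, 37 to 67 and 138 to 577, with 2641 to 4990 for the mean. The interactions ran from 1549 to 6099, 202 to 353, 14 to 118 and 6 to 153. Depth limits genes near the floor of 3 read pairs.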

Other observations

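The Gene Ontology tests and those of a carried Pst response, the harvest hour, copies and genome segments were chosen only after the result was seen. Of 33 sterol synthesis genes 18 were higher in mock-inoculated βca3 at ambient CO2, where 2.0 were expected (Fisher adjusted p = 2.8e-11), and 12 at elevated CO2, where 1.0 were (1.7e-07), all 12 shared. Camera with an estimated correlation gave adjusted p = 0.37 and 1.0. Delta14-sterol reductase (Solyc09g009040.3) was higher by 2.55 and 1.70. After Pst 0 were higher at ambient CO2 and 3 higher and 1 lower at elevated CO2, and 10 of the 33 Pst by genotype interactions were negative and 0 positive. Of 107 genes of response to chitin 35 were lower in mock-inoculated βca3 at elevated CO2, 2.1 being expected (1.9e-30, and adjusted p = 1.0 with an estimated correlation), and 44 were higher at elevated CO2 in mock-inoculated WT, 7.8 being expected (9.4e-20, and adjusted p = 0.58 with an estimated correlation). Both share the WT libraries at elevated CO2. In mock-inoculated βca3 24 were also higher and 1 lower at elevated than at ambient CO2, the CO2 by genotype interaction passed for 1, and between genotypes at ambient CO2 10 were lower and 5 higher in βca3. Markers of other cell types passed in few comparisons: trichome 0 and pollen 0 of 17, phloem 1, and the stomata list 2 (βca3 in mock leaves at elevated CO2, median -0.19, adjusted p = 0.046, and adjusted p = 0.72 with an estimated correlation, and CO2 by genotype, median -0.31, adjusted p = 0.013, and adjusted p = 0.36 with an estimated correlation). That list holds a mitochondrial stomatin-like protein (Solyc03g080050.3), without which adjusted p = 0.042 and 0.022, or 0.72 and 0.48 with an estimated correlation.

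For 1392 genes higher at elevated CO2 in mock-inoculated WT, a response to Pst carried by mock plants would need the genes of that response to be higher too. The 200 genes with the largest rise under Pst in βca3 had a median CO2 change of 0.07, with quartiles of -0.33 and 1.53. Of the 1392, 991 rose and 91 fell under Pst in βca3, where independent lists give 492 that rise. Members going both ways, a carried response cannot be told apart from CO2, and neither can a harvest hour that differed between CO2 levels, since each level is one setting. Of 11 clock genes 7 were lower by sign in all 3 other CO2 comparisons, 3 of them passing in each.

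Of 30 genes differing the same way between genotypes in all 4 conditions, 19 share a description with another gene. The summed level of such genes moved with the gene by over 2 SE for 16 of the 19, which argues there against reads moved between near-identical copies as the whole cause. It stays open for 3, the BED protein Solyc04g057787.1, whose sum stayed near level, and another BED protein (Solyc04g056748.1) and Solyc02g067610.1, whose sums moved the other way. Of the 30, 10 had a neighbour in the set (highest of 10000 random sets 8, permutation test, p = 1e-04). With 1 gene per description it was 4 of 27 (highest 7, permutation test, p = 0.04). Models of 1 locus would count too, so whether genome segments differ between the lines stays open.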
